A study of Mus musculus with 4 samples.

How the data were processed

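Gene expression was measured on 4 oligonucleotide arrays hybridised with RNA from laser-captured structures of the fetal mouse kidney at stage E15.5 (Theiler stage 23). Laser capture cuts chosen cells out of stained frozen sections under a microscope. Per the labels' protocols, the mice were of the outbred CD-1 stock, each array held a pool of about 50 sections from 5 kidneys, and the RNA was amplified over 2 rounds and labelled with biotin. Amplification of this kind copies the 3' end of a transcript more fully than its 5' end, so probe sets far from the 3' end read low in degraded RNA. The labels do not say how the structures were recognised in the sections, nor whether pools shared kidneys or litters. All p-values therefore measure the spread between these samples only, which may be partly technical.

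The deposited values were probe set intensity values on a linear scale, made with the array software GCOS per the submitters' processing notes. Its version and algorithm are not given in the sources used here. In the deposited table the mean after trimming 2% of the values at each end was 1500 in all 4 arrays, so each array had been scaled to a common trimmed mean. The medians still differed, from 206.9 to 526.5 signal units. Detection calls and scanner images were not used here. For arrays the number of samples limits the precision, and here 1 array stood for the collecting duct.

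The 4 arrays were quantile normalized on the linear scale, and log2(signal + 109.6) was taken, 109.6 being the 25th percentile of the common distribution. A fold on this scale understates the change of a gene with low signal, and where 1 side is dim its size depends on the offset. After normalization 64 control probe sets were left out, which left 45037 of 45101. Of these, 34945 had 1 gene symbol in the platform table, 932 had several and 9160 had no entry there. Entrez numbers matched 34741 of the probe sets with 1 symbol to the RefSeq gene table of assembly GRCm38, used only for names, and 0 symbols needed an update. Probe sets with several symbols or none were not tested. For a gene with several probe sets the one with the highest mean over the 4 arrays was used. In a refit without an array, normalization and this choice were made anew over the arrays left. Genes with a mean log2 value under 8.416, the 40th percentile of all probe sets, were not tested. This left 12642 of 18193 genes. No genome build was named for the array, so no coordinates are given.

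The collecting duct array was compared with the 3 anlage arrays with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom, all from the anlage arrays, and 4.04 prior degrees of freedom. A refit without 1 anlage array had 1 residual degree of freedom, from the 2 anlage arrays left. The lone collecting duct array was assumed to vary like the anlage arrays. An exact permutation test of 1 array against 3 cannot give a p below 0.25, so none was used for single genes.

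Before the data were examined, 23 gene lists with 482 members were fixed, for the captured segments, for neighbouring cell types the laser could have caught and for pathways. They covered collecting duct and ureteric stalk, ureteric tip, loop of Henle and thick ascending limb, distal convoluted and connecting tubule, intercalated cell, early nephron, proximal tubule, podocyte, cap mesenchyme, interstitial stroma, endothelium, erythroid, macrophage and leukocyte, pan-epithelial, cell cycle, Notch pathway, Wnt ligands and targets, FGF and RET signalling feedback, hypoxia and glycolysis, mitochondrial respiratory chain, immediate early and stress, extracellular matrix and basement membrane, and sex-linked genes. Some genes stand in more than 1 list. The 22 lists with at least 5 tested members were tested against all other genes with camera in limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the residuals. A list's shift is the median difference of its members minus the median of all genes. Members of a list were also adjusted over the list alone, with no correction over the 23 lists. A lone member past that threshold in a list can therefore arise by chance.

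Genes were named by a rule fixed before the data were examined. It took genes past the threshold over all genes, up to 12 per direction, then up to 4 members of each list with the largest absolute difference, then a fixed set of segment genes where tested. Egf, genes called only with an array left out, other members that passed over their list alone, and genes named in the closing part were chosen after their values were seen.

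The fit was tested on simulated data with 12642 genes, 200 of them changed, over 10 runs at the spread seen between the arrays. It recovered 0% of genes changed by 1 on the log2 scale, 0.8% at 2, 32.2% at 4 and 83.4% at 6, with 2.2 false calls per run. A list shifted by 2 was called in 100% of runs with the preset correlation, with 0 other lists called. With the estimated correlation it was called in 0% of runs. Simulated genes varied independently of each other. In the data the estimated correlation was 0.178 within the collecting duct list and 0.255 within the loop list. The simulation therefore does not measure false calls for lists with correlated members. Alternatives covered the normalization, the offset, the filter, the choice of probe set, the moderation, a test for a fold above 1.5, the correlation between genes, and leaving out each anlage array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.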

Results

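Transcripts were profiled in structures captured by laser from the developing mouse kidney at stage E15.5 (E counts embryonic days). The cortical collecting duct, the outer part of the branched urine-collecting epithelium that grows from the ureteric bud, was represented by 1 array, numbered replicate 3. The anlage of the loop of Henle, the nephron segment that later forms the thick ascending limb, was represented by 3 arrays, numbered 1 to 3. The comparison asks which genes mark each structure at this stage.

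The arrays differed in RNA quality signs within the anlage group. Signal from the 18S ribosomal RNA 3' control was 150115 in the collecting duct array and 196512, 16574 and 110325 in anlage arrays 1, 2 and 3. The 3' to 5' signal ratio of Gapdh, which grows as transcripts are shortened, was 12.05 in the collecting duct array against 10.3, 54.1 and 26.0 in the anlage arrays. For beta-actin the ratio was 3.56 against 3.06, 6.41 and 5.42, and for the transferrin receptor 1.38 against 1.42, 3.28 and 1.55. Across the 12642 tested genes the log2 values of anlage arrays 1 and 2 correlated at r = 0.813, those of arrays 1 and 3 at r = 0.886 and those of arrays 2 and 3 at r = 0.915. The collecting duct array correlated with anlage arrays 1, 2 and 3 at r = 0.902, 0.868 and 0.902. Genes are not independent replicates, and these correlations only describe the arrays. No pair of arrays shared more than 3 identical values.

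**Figure D1:**
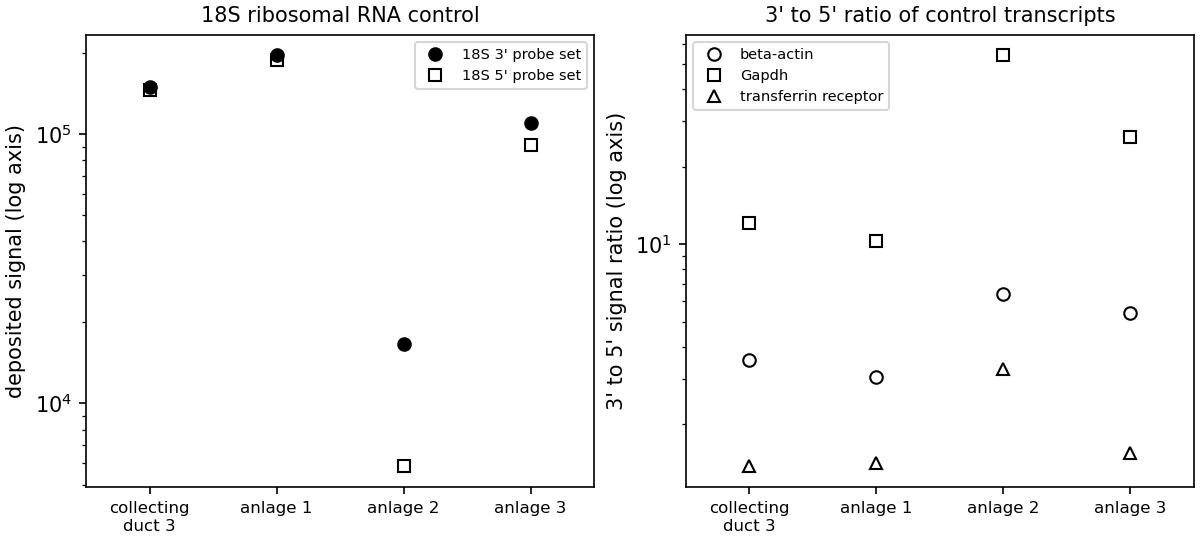
RNA quality signs in the 4 arrays, 1 point per array and control, with log vertical axes. On the left, the deposited signal of the 18S 3' and 5' control probe sets is lowest in anlage array 2, at 16574 and 5848. On the right, the 3' to 5' signal ratios of beta-actin, Gapdh and the transferrin receptor are highest in anlage array 2, at 6.41, 54.1 and 3.28.

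Genes of collecting duct epithelium were higher in the cortical collecting duct array than in the loop of Henle anlage. Transcripts for the gamma and beta subunits of the epithelial sodium channel, Scnn1g and Scnn1b, were higher by 4.11 ± 1.04 and 2.48 ± 0.57 (SE) on the log2 scale. Gata3, a transcription factor of the ureteric lineage, stood at a log2 value of 15.17 in the collecting duct and 11.64 ± 1.06 (SD, n = 3) in the anlage, an 11.5-fold difference. Wnt9b, a ligand of the ureteric epithelium that acts on nephron progenitors, was 11.4-fold higher, though its log2 difference fell to 1.88 with the mean of all probe sets of the gene. The anlage mean of Scnn1g, 8.07, lay under the log2 value of 8.416 below which genes were left out as dim, and its difference ranged from 3.11 to 5.33 across settings. Without anlage array 3 the difference of Gata3 was 2.89 in place of 3.53.

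Of 24 tested members of the collecting duct and ureteric stalk list, 23 had a higher value in the collecting duct array, and 20 lay above all 3 anlage arrays. Adjusted over the list alone, 10 members were higher and 1 lower, while 0 passed over all 12642 genes. Besides Scnn1g, Scnn1b, Gata3 and Wnt9b, the members that passed were the ETS-family transcription factors Elf5 and Ehf, the sodium pump regulator Fxyd4, the water channel Aqp4, the glucocorticoid-inactivating enzyme Hsd11b2 and the vasopressin receptor Avpr2. Elf5 was 17.2-fold higher, at 14.50 against 10.40 ± 1.13 (SD, n = 3), with an adjusted p of 0.0219 over the list. Fxyd4 was 13.4-fold higher, at 13.98 against 10.24 ± 0.49 (SD, n = 3), with an adjusted p of 0.0183 over the list. Aqp4 was higher by 3.17 ± 0.83 (SE), Ehf by 3.01 ± 0.75, Hsd11b2 by 2.23 ± 0.70 and Avpr2 by 1.79 ± 0.54. Without anlage array 3 the adjusted p over the list became 0.0977 for Hsd11b2 and 0.12 for Avpr2, and the difference of Elf5 was 3.495 in place of 4.11. With the mean of all probe sets of a gene that of Elf5 was 2.95.

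Several collecting duct genes did not pass. Aqp2, the vasopressin-regulated water channel, differed by 0.82 ± 0.51 (SE), Wnt7b by 0.61 ± 0.55 and the keratin Krt19 by 0.76 ± 0.91. Across settings the difference of Krt19 ranged from 0.22 to 1.35. Calb1, a calcium-binding protein, differed by 1.32 ± 1.40, and its probe sets disagreed in sign, from −0.03 to 1.67. Its anlage values were 11.50, 14.86 and 11.30, array 2 being the highest of the 4 arrays. Hoxb7 lay below the filter on dim probe sets. Nrcam, a cell adhesion molecule, went against the list, at 8.01 in the collecting duct and 11.21 ± 0.55 (SD, n = 3) in the anlage (adjusted p = 0.0195 over the list). Its probe sets differed by −3.20 to −1.48.

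As a group the list lay 1.78 above the median of all genes (camera, adjusted p = 6.27e-20 with the preset correlation). The call was lost when the correlation between genes was estimated. That setting also missed a true shift in every simulated run, so the loss cannot decide whether the list differs. The list mean was 12.06 in the collecting duct array and 9.94, 10.77 and 10.07 in anlage arrays 1, 2 and 3. Within the anlage this was the order of the Gapdh and beta-actin ratios. The collecting duct array, with ratios between those of anlage arrays 1 and 3, did not follow that order. Scaling the arrays to a common median in place of quantile normalization left 6 members higher over the list alone.

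Genes of the loop of Henle and thick ascending limb showed the opposite pattern. Kcnj1, the apical potassium channel of the thick limb, was lower in the collecting duct array (−5.52 ± 1.05 (SE) on the log2 scale), and so was Umod, which encodes uromodulin (−5.20 ± 1.18). Slc12a1, the sodium-potassium-chloride cotransporter of this segment, was 14.4-fold lower. The homeobox gene Irx2 differed by −3.87 ± 0.78 and the tight junction gene Cldn10 by −3.35 ± 0.83. The collecting duct values of Kcnj1, Umod, Irx2 and Cldn10 lay under 8.416, so the size of these differences depends on the offset. All come from the brightest probe set of each gene. The differences were smaller in another probe set of Kcnj1 (−1.66, against −5.52) and of Slc12a1 (−1.80, against −3.85, and −2.82 with the mean of its probe sets), and across the settings tried that of Kcnj1 ranged from −7.15 to −3.59. The difference of Umod was −5.88 without anlage array 2.

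Of 18 tested members of the loop list, 14 had a lower value in the collecting duct array, and all 14 lay below all 3 anlage arrays. Adjusted over the list alone, 12 were lower and 0 higher, while 0 passed over all genes. Kcnj1 stood at 7.31 against 12.83 ± 1.39 (SD, n = 3), with an adjusted p of 0.0112 over the list. Umod stood at 8.34 against 13.54 ± 1.63 (SD, n = 3), with an adjusted p of 0.0162 over the list. Slc12a1 stood at 10.44 against 14.29 ± 0.92, and Irx2 at 8.09 against 11.96 ± 0.89, both with an adjusted p of 0.0112 over the list. The other members that passed were Tmem52b (−2.94 ± 0.52, SE), the claudin Cldn16 (−2.89 ± 0.88), the secreted BMP and Wnt antagonist Sostdc1 (−2.77 ± 0.96, and −1.46 in another probe set), the prostaglandin receptor Ptger3 (−2.60 ± 0.90), the calcium-sensing receptor Casr (−2.29 ± 0.54), the chloride channel subunit Bsnd (−2.06 ± 0.64) and Irx1 (−1.91 ± 0.57). Without anlage array 3 the adjusted p over the list became 0.0508 for Sostdc1, 0.0732 for Ptger3, 0.0676 for Bsnd and 0.102 for Irx1. The difference of Ptger3 was −3.47 without anlage array 1, and that of Sostdc1 −3.45 without anlage array 2. The collecting duct values of Cldn16 (7.59), Casr (7.51) and Ptger3 (8.41) also lay under 8.416, so the size of their differences depends on the offset.

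Not all loop genes passed. Irx3 stood at 12.11 in the collecting duct and 11.88 ± 0.45 (SD, n = 3) in the anlage, and its difference of 0.22 ± 0.57 (SE) changed sign under some settings. Pou3f3 differed by −0.71 ± 0.43 (SE), and its probe sets disagreed in sign, from −0.71 to 0.40. Egf, a growth factor of the mature distal nephron, had a value 1.56 ± 0.60 higher in the collecting duct array and did not pass (adjusted p = 0.056 over the list).

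The loop list lay −2.38 from the median of all genes (camera, adjusted p = 1.55e-12 with the preset correlation). This call too was lost with an estimated correlation, a setting that cannot decide for the same reason. The list mean was 9.54 in the collecting duct array and 12.05, 11.13 and 11.84 in anlage arrays 1, 2 and 3, so that array 2 lay nearest to the collecting duct on both segment lists. Within the anlage this was the reverse of the order of the Gapdh and beta-actin ratios, which the collecting duct array again did not follow. Testing for a fold above 1.5 left 7 members lower over the list alone.

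**Figure D2:**
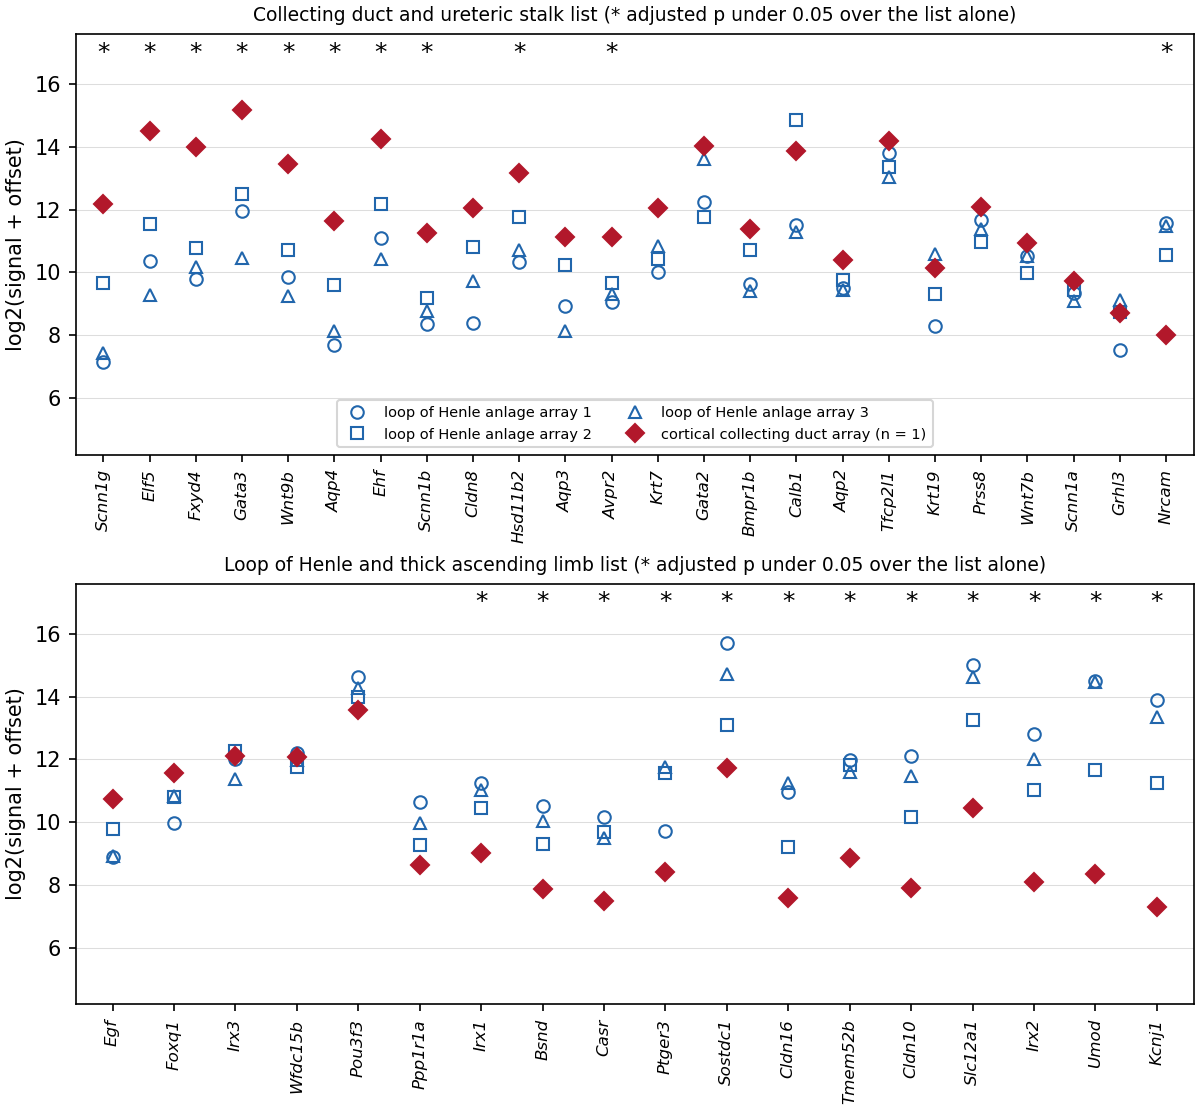
Log2(signal + offset) of each tested member of the collecting duct list (top) and the loop list (bottom), with the single collecting duct array as filled diamonds and the 3 anlage arrays as open symbols. Stars mark members past an adjusted p of 0.05 over the list alone, 11 in the collecting duct list (10 higher, and Nrcam lower) and 12 in the loop list, all lower.

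Over all 12642 genes, limma called 0 genes higher and 0 lower in the collecting duct array at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 149 higher and 282 lower, together 431, where chance gives 632. That total was 1401 without anlage array 1 and 192 without anlage array 3. Without anlage array 2, limma called 3 genes higher (Shh, Scnn1g and Elf5) and 11 lower (Sim2, Umod, Afp, Kcnj1, Actc1, Slc12a1, Slc9a3, Spon1, Has3, Sostdc1 and Irx2). That refit took its spread from anlage arrays 1 and 3 alone, with 1 residual degree of freedom. For Actc1 the array left out lay close to the collecting duct array. With all arrays, the collecting duct array lay above all 3 anlage arrays for 2185 genes and below all 3 for 3070, which is 41.6% of genes where chance gives 50%. With anlage array 1, 2 or 3 set as the single array instead, 2, 9 and 9 lists passed with the preset correlation, against 6 in the real grouping, and 0 lists passed with an estimated correlation in any of these. Such splits place the collecting duct array among the grouped arrays.

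Most genes shared by epithelia in general had higher values in the collecting duct array, though few passed. Of 22 tested members of the pan-epithelial list, 18 had a higher value and 15 lay above all 3 anlage arrays. Adjusted over the list alone, 3 were higher and 0 lower, and 0 passed over all genes. These were the tight junction gene Cldn3 (2.51 ± 0.55, SE) and the simple-epithelial keratins Krt18 (2.25 ± 0.48) and Krt8 (1.84 ± 0.42), each with an adjusted p of 0.0349 over the list, which became 0.174 without anlage array 3. Mal2 differed by 2.44 ± 0.94 and did not pass. The list shift was 0.80 (camera, adjusted p = 5.71e-09 with the preset correlation, and adjusted p = 0.465 with an estimated correlation). The list means of the anlage arrays were close, at 12.28, 12.18 and 12.16, against 13.02 in the collecting duct array.

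Endothelial genes had lower values in the collecting duct array for all 18 tested members, 13 of them below all 3 anlage arrays. Adjusted over the list alone, 0 passed, as over all genes. Tek and Kdr, receptors of vascular endothelium, differed by −2.57 ± 0.78 and −2.02 ± 0.73 (SE), the transcription factor Erg by −1.62 ± 0.78 and Cd34 by −1.58 ± 1.16. Pecam1 lay below the filter. The list shift was −0.94 (camera, adjusted p = 1.89e-07 with the preset correlation, and adjusted p = 0.627 with an estimated correlation). The list mean was 9.41 in the collecting duct array and 9.99, 10.85 and 10.72 in anlage arrays 1, 2 and 3, lowest within the anlage in array 1, which also had the lowest Gapdh and beta-actin ratios.

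Proximal tubule genes had lower values for 22 of 24 tested members, and 0 passed over the list alone or over all genes. The sodium pump regulator Fxyd2 stood at 9.12 against 12.12 ± 1.11 (SD, n = 3). Amn, a partner of the receptor cubilin, differed by −1.48 ± 0.50 (SE), the water channel Aqp1 by −1.37 ± 0.75, the organic anion transporter Slc22a6 by −1.28 ± 0.58 and the transcription factor Hnf4a by −0.96 ± 0.59. The list shift was −0.55 (camera, adjusted p = 0.000215 with the preset correlation, and adjusted p = 0.536 with an estimated correlation). The list mean was 9.11 in the collecting duct array and 9.55, 10.06 and 9.83 in anlage arrays 1, 2 and 3, which within the anlage is the order of the Gapdh and beta-actin ratios. As in the segment lists, the collecting duct array did not follow it, and 3 arrays can fall in such an order by chance.

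Cell cycle genes had lower values for 29 of 34 tested members, and 0 passed over the list alone or over all genes. The spindle genes Mad2l1, Nusap1, Bub1 and Kif11 differed by −1.03 ± 0.48, −0.89 ± 0.56, −0.87 ± 0.68 and −0.81 ± 0.52 (SE), and the probe sets of Nusap1 and of Kif11 disagreed in sign. The list shift was −0.34 (camera, adjusted p = 0.00122 with the preset correlation, and adjusted p = 0.627 with an estimated correlation). The call was also lost when arrays were scaled to a common median (adjusted p = 0.075), although the shift there was −0.43. The list mean was 12.56 in the collecting duct array and 12.83, 13.16 and 12.94 in anlage arrays 1, 2 and 3, again in the order of these ratios within the anlage.

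The ureteric tip list was not called (6 of 13 members with a higher value, adjusted p = 0.646). Its camera direction was up and its mean 0.03, while its median was −0.02. The organic anion transporter Slco4c1 passed over the list alone, at 12.01 against 8.29 ± 0.86 (SD, n = 3), and 0 members passed over all genes. Its difference of 3.72 was 4.41 without anlage array 1 and 3.10 without anlage array 2, and 1.74 with the mean of all probe sets of the gene. Ret, the receptor that drives ureteric branching, differed by 0.14 ± 1.40 (SE) and Wnt11 by −0.02 ± 0.64, and both changed sign under some settings. The signalling feedback gene Dusp6 differed by −1.82 ± 1.16, Etv5 by −1.39 ± 0.95 and Lhx1 by −1.29 ± 0.85, the probe sets of Etv5 and of Lhx1 disagreeing in sign. Across settings these differences ranged from −2.66 to −0.92 for Dusp6, from −2.06 to −0.33 for Etv5 and from −1.77 to −0.48 for Lhx1. In anlage arrays 1, 2 and 3 Dusp6 stood at 11.56, 14.76 and 12.90.

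In the distal convoluted and connecting tubule list, 6 of 10 members had a higher value and the list was not called (adjusted p = 0.35). The transcription factor Tfap2b was 7.67-fold lower at 9.82 against 12.76 ± 0.39 (SD, n = 3) and was the 1 member that passed over the list alone (adjusted p = 0.0171), with 0 over all genes. Its other probe set differed by −0.74, and the mean of its probe sets by −1.84. In the refit without anlage array 2, which chose the brightest probe set anew, the difference of Tfap2b was −2.12 in place of −2.94. With an anlage SD of 0.39 the left-out array alone would not account for this change, so another probe set may have been used. Tfap2b did not pass over the list in that refit, nor without anlage array 3. The sodium-calcium exchanger Slc8a1 differed by 2.27 ± 0.71 (SE), Tfap2a by 1.26 ± 0.97 and the calcium pump Atp2b1 by 0.95 ± 0.64, the last changing sign under some settings. In the intercalated cell list, 2 of 5 members had a higher value (adjusted p = 0.747). The proton pump subunits Atp6v1c2, Atp6v1b1 and Atp6v0d2 differed by −1.23 ± 0.68, −1.23 ± 0.96 and 0.28 ± 0.75, and carbonic anhydrase Car2 by 0.99 ± 0.77. The sign for Atp6v0d2 changed under some settings. Without the filter on dim probe sets the list passed in the upward direction with the preset correlation (shift 0.28). The estimated correlation was tried only with the filter, where the list did not pass.

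Lists of earlier nephron structures were not called. The early nephron list had 6 of 17 members with a higher value (adjusted p = 0.0891), with Cdh6 at −1.61 ± 0.53 (SE), the cyclin Ccnd1 at −1.32 ± 0.39, the Notch target Hes5 at −1.23 ± 0.95 and Wnt4 at 0.58 ± 0.77. The cap mesenchyme list, for nephron progenitors, had 4 of 15 (adjusted p = 0.26), with Meox1 at −1.41 ± 0.68, Osr1 at −1.01 ± 0.67, Six2 at −0.73 ± 0.68 and Itga8 at −0.64 ± 0.58. The podocyte list had 8 of 14 (adjusted p = 0.747), with the matrix protein Npnt at 2.55 ± 0.85, the phosphatase Ptpro at −2.04 ± 0.63, Nes at 0.97 ± 0.93 and Foxc2 at −0.93 ± 0.71. The probe sets of Npnt and of Nes disagreed in sign, and Nphs1 lay below the filter. In these 3 lists 0 members passed over the list alone. Without anlage array 3 the early nephron and cap mesenchyme lists passed with the preset correlation (adjusted p = 0.00986 for both). The early nephron list also passed without the filter on dim probe sets (adjusted p = 0.0172) and with probe sets of an s, x or a suffix left out (adjusted p = 0.0495).

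Interstitial stroma genes were not called as a group (13 of 29 with a higher value, adjusted p = 0.747). The camera direction was up, while the list's median was −0.07 and its mean −0.13. The stromal matrix gene Lum differed by −2.03 ± 2.28 (SE), smooth muscle actin Acta2 by −1.73 ± 1.15, the receptor Pdgfrb by −1.48 ± 0.51, Smoc2 by 1.59 ± 0.64 and the stromal progenitor gene Foxd1 by 0.36 ± 0.55. Erythroid genes had lower values for 5 of 5 members (adjusted p = 0.168), with Slc4a1 at −0.69 ± 0.70, Alas2 at −0.66 ± 0.52, Hbb-b2 at −0.58 ± 0.53 and Epor at −0.46 ± 0.49. Macrophage and leukocyte genes had lower values for 8 of 11 (adjusted p = 0.126), with Tyrobp at −1.12 ± 0.85, Csf1r at −0.89 ± 0.60, Cd68 at −0.71 ± 0.49 and C1qb at −0.65 ± 0.54. Without anlage array 3 the erythroid and the macrophage and leukocyte lists passed with the preset correlation (adjusted p = 0.0356 for both). The macrophage and leukocyte list also passed when all probe sets of a gene were averaged (shift −0.44, adjusted p = 0.0257). In these 3 lists 0 members passed over the list alone.

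**Figure D3:**
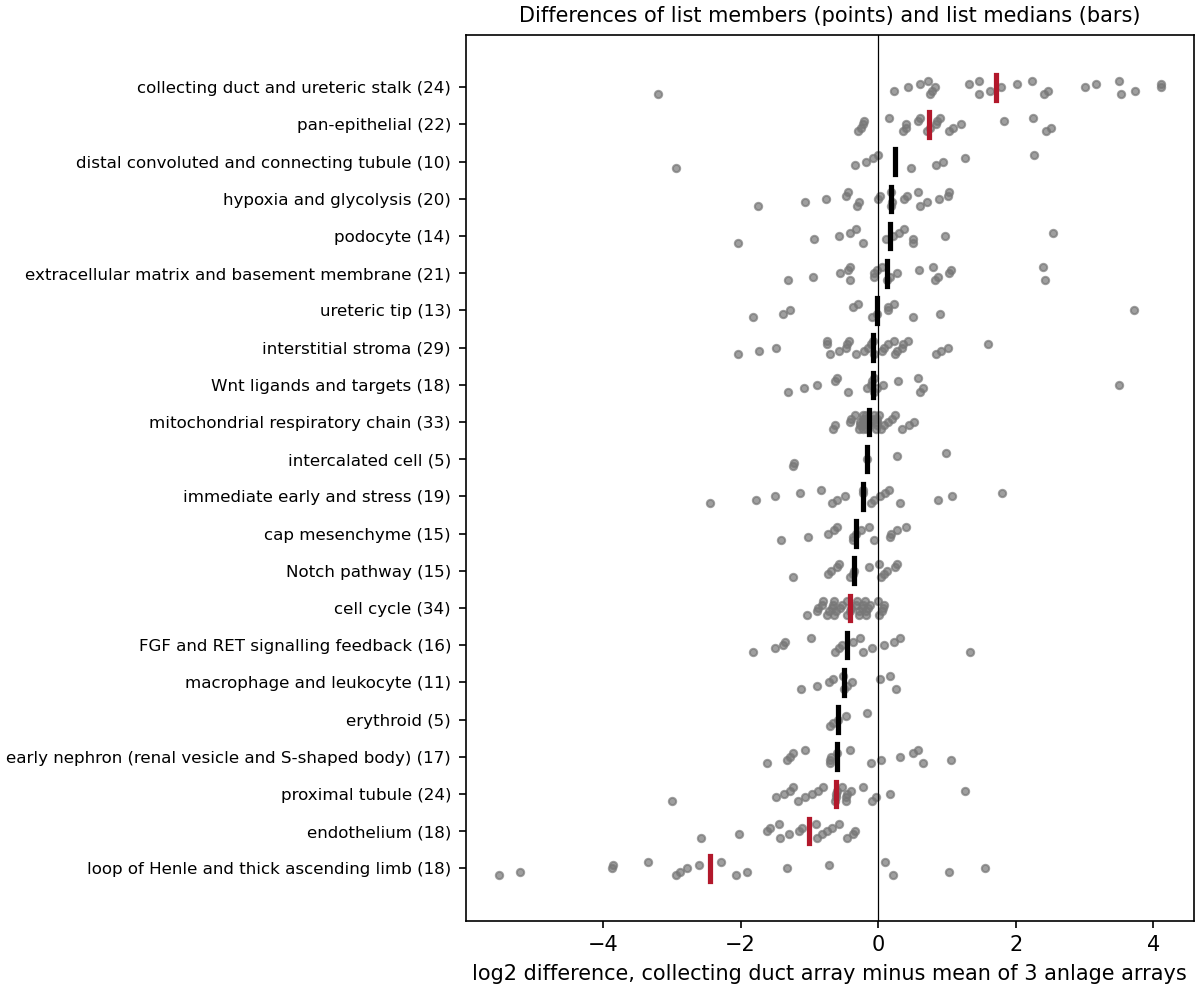
Log2 difference, collecting duct array minus the mean of the 3 anlage arrays, for every tested member (grey points) of each list, with the number of members in brackets. Bars are list medians, red where camera passed with the preset correlation, and range from −2.44 for the loop list to 1.71 for the collecting duct list.

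Of the pathway lists, 0 were called besides the cell cycle. Wnt ligands and targets had a higher value for 6 of 18 members (adjusted p = 0.976), with a camera direction of up and a mean of 0.02 but a median of −0.08. Wnt9b passed over that list alone (adjusted p = 0.0438, and 0.113 without anlage array 3). Lgr5 differed by −1.32 ± 0.83 (SE), Sfrp2 by −1.07 ± 0.56 and Fzd8 by −0.89 ± 0.59. The Notch list (6 of 15, adjusted p = 0.399) held Nrarp at −0.72 ± 0.51, Hey1 at −0.68 ± 0.72 and Dll1 at −0.59 ± 0.53. The FGF and RET feedback list (4 of 16, adjusted p = 0.232) held the immediate early gene Egr1 at −1.49 ± 0.59 and Il17rd at −1.36 ± 1.00. It passed without anlage array 3 with the preset correlation (shift −0.57). The estimated correlation was tried only with all arrays, where this list did not pass. In the immediate early and stress list (7 of 19, adjusted p = 0.417) the phosphatase Dusp1 differed by −2.45 ± 0.60, Hspa1a by 1.81 ± 0.99 and Gadd45a by −1.78 ± 1.08.

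Basement membrane and metabolic lists held differences in both directions. In the extracellular matrix list (12 of 21 with a higher value, adjusted p = 0.232) the collagen chain Col4a4 differed by 2.43 ± 1.13 (SE), the laminin chains Lama5 by 2.40 ± 0.57, Lama1 by −1.30 ± 0.53 and Lamc1 by 1.06 ± 1.44. Lamc1 changed sign under some settings and between its probe sets. With the preset correlation the list passed when all probe sets of a gene were averaged (shift 0.45 in place of 0.20). The estimated correlation was tried only in the main setting, where the list did not pass. In the hypoxia and glycolysis list (12 of 20, adjusted p = 0.569) Egln3 differed by −1.75 ± 0.89, Pfkp by −1.07 ± 0.79, Vegfa by 1.04 ± 1.09 and Pdk1 by 1.01 ± 0.56. In the mitochondrial list (9 of 33, adjusted p = 0.569) Uqcrfs1 differed by −0.65 ± 0.49, cytochrome c (Cycs) by −0.63 ± 0.32, Ndufa5 by 0.53 ± 0.39 and Sdhd by 0.45 ± 0.96, the last changing sign between its probe sets. Apart from Wnt9b, 0 members of these 7 pathway lists passed over their list alone or over all genes.

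The labels give the sex of the pools as unknown. Xist, expressed from the inactive X chromosome, stood at 16.95 in the collecting duct array and 16.60 ± 0.28 (SD, n = 3) in the anlage. The Y-linked Eif2s3y stood at 9.85 against 10.54 ± 0.27, and Uty at 8.41 against 8.61 ± 0.48. With 3 tested members this list was too small for camera, and 0 members passed over the list alone.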

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

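The alternatives were fixed before the data were examined. Under all of them except leaving out 1 anlage array, limma called 0 genes in either direction over all genes. Leaving out each anlage array in turn gave 0 to 3 genes higher and 0 to 11 lower, the highest counts coming without anlage array 2, where the smallest adjusted p was 0.00116. The collecting duct list shift of 1.78 ranged from 1.85 to 2.11 with an array left out, and the loop list shift of −2.38 from −2.32 to −2.01. Both kept their sign and their call with the preset correlation in every setting where camera was run. With the correlation estimated, the same shifts of 1.78 and −2.38 lost the call (adjusted p of 0.474 and 0.536). On simulated data with genes drawn independently, that setting missed a true shift in every run. The simulation does not show how often the preset correlation falsely calls lists of correlated genes. The 10 collecting duct members higher over their list became 8 to 14 with an array left out and 6 with arrays scaled to a common median. The 12 loop members lower over theirs became 8 to 13, and 7 when a fold above 1.5 was tested. The causes of these changes were not tested. Of 29 list memberships past the threshold over a list, 18 stayed past it whichever array was left out. The intercalated cell list reversed from −0.09 to 0.275 without the filter on dim probe sets, where 18193 genes were tested. Of 99 named genes, 91 kept their sign in every setting and 8 did not (Atp2b1, Atp6v0d2, Irx3, Lamc1, Nes, Ret, Sdhd and Wnt11). Scaling to a common median moved the median of all genes from −0.06 to −0.24, and leaving out anlage array 1 moved it to −0.19, so list shifts are given relative to it. Camera was not run when all probe sets were tested or for the fold test. No paired analysis was possible because the groups share only 1 replicate number. Precision is limited by 4 arrays, and signal over background was not analysed here beyond the filter on dim probe sets.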

Other observations

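The tests of explanations in this part were chosen after the results were seen, and so were the genes named, while the refits without an array were planned. Outside the fixed lists, the genes with the smallest p include the following. Sim2, a transcription factor, stood at 8.82 in the collecting duct array and 14.51 ± 1.25 (SD, n = 3) in the anlage. Slc9a3, an apical sodium-proton exchanger, stood at 8.60 against 12.89 ± 0.73, and Stk39, a kinase that acts on cation-chloride cotransporters, at 8.55 against 12.42 ± 0.28. The hyaluronan synthase gene Has3 differed by −4.43 ± 0.61 (SE), Spon1 by −4.35 ± 0.65 and the potassium channel gene Kcnj5 by −2.43 ± 0.50. In the other direction, Ptprj differed by 3.69 ± 0.76, Lrrn4 by 3.14 ± 0.60, Tmem30b by 2.90 ± 0.52 and Plet1 by 2.88 ± 0.63. The collecting duct values of Has3 (7.23), Spon1 (7.80) and Kcnj5 (7.10) lay under 8.416, as did the anlage means of Ptprj (8.37) and Lrrn4 (7.66). The size of their differences depends on the offset. Over all genes none of these passed in limma with all 4 arrays (smallest adjusted p 0.9999). Without anlage array 2, Sim2 (−6.18 ± 0.58, adjusted p = 0.00116), Slc9a3 (−4.45 ± 0.64), Spon1 and Has3 passed. Shh, a ligand secreted by collecting system epithelium, then passed in the other direction (5.21 ± 0.67, adjusted p = 0.00678).

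The anlage arrays differed among themselves in some genes of the interstitial stroma list. Those given here were picked from its 29 tested members by their values, and the others need not follow the same order. In arrays 1, 2 and 3 Lum stood at 8.12, 10.10 and 14.66, Dcn at 12.17, 10.53 and 14.80, Acta2 at 13.33, 13.39 and 16.17, and Tagln at 7.54, 9.84 and 11.45. The interstitial stroma list mean was 11.62, 11.98 and 12.79 in these arrays, against 12.001 in the collecting duct array. Actc1, a muscle actin, stood at 14.01, 8.89 and 14.24, against 8.68 in the collecting duct array, and alpha-fetoprotein (Afp) at 15.54, 12.63 and 14.72, against 9.31. No explanation was tested for these values.

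For the opposite movement of the collecting duct and loop lists, RNA quality and other cells in the pools were weighed. Of 42 segment list members, 34 (81%) lay outside the anlage range in the direction of their list. The share expected was 20.3%, from the shares of all genes above and below that range, weighted by the sizes of the lists. The collecting duct array lay between the anlage arrays in the beta-actin and Gapdh ratios. Quality as read by these ratios is thus argued against as the whole cause. The 18S signal of the collecting duct array also lay between theirs, but the order of deposited 18S signals may reflect the scaling of each array. In the collecting duct array and anlage arrays 1 and 3 they ranked as the cre spike-in control did (173909, 226987 and 140825). The transferrin receptor ratio of the collecting duct array, 1.38, lay just below those of the anlage arrays (1.42, 3.28 and 1.55). By that control the test cannot decide, and the controls were chosen after the values were seen. For the collecting duct list, more non-epithelial cells in the anlage pools stay open as an explanation. That list exceeded the pan-epithelial list by 0.98 (means of 1.80 and 0.82), which is under 2 SE over arrays (SE 0.552). Such cells would lower epithelial genes in the anlage. They would thus not account for the loop list, which was higher there (shift of −2.38 in the collecting duct array). With each of the 4 arrays set as the single one, 1 split, the real one, gave 23 segment list members past the threshold and the highest other gave 0, but 4 splits are too few for a share under 0.05, and camera with the preset correlation also called the loop list with anlage array 1 as the single one (shift 1.52, adjusted p = 0.00125) and the collecting duct list with anlage array 3 (−0.88, adjusted p = 3.21e-05). The other splits place the collecting duct array among the grouped arrays, which widens the residual spread of the segment list genes. A count of 0 was therefore likely in advance, and neither these counts nor these calls can decide on chance. The difference of segment that the labels name may account for the pattern, as a hypothesis.

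The lower endothelial values in the collecting duct array were weighed against a lower share of all non-epithelial cells and against anlage array 2. The stroma list mean exceeded the endothelium list mean by 0.98 (SE 0.54 over arrays), with means of −0.13 and −1.11. The erythroid and the macrophage and leukocyte lists had shifts of −0.51 and −0.43, which were −0.33 and −0.25 without anlage array 1. A lower share of every non-epithelial type therefore stays open. Without anlage array 2 the endothelium list shift was −0.83, against −0.94 with it, so that array was not the whole source. A different number of capillaries caught with each structure may be the source, which these data did not test. The call rests on the preset correlation.

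Anlage array 2 differed from anlage arrays 1 and 3 in the values of several lists, though over the tested genes its correlation with array 3 (r = 0.915) exceeded that of arrays 1 and 3 (r = 0.886). Both explanations weighed remain open. Of 6 lists for neighbouring structures, 5 deviated upward in array 2 beyond the 95th percentile of 10000 random lists matched on expression. These 6 lists were chosen after the values were seen. The loop list deviated by −0.82, while the proximal tubule list stayed below its 95th percentile (0.37 against 0.50). Other nearby cell types did not pass theirs. Distal convoluted and connecting tubule lay at percentile 52.52, intercalated cell at 4.54, interstitial stroma at 2.08 and endothelium at 94.15. Random lists drew genes independently, so percentiles of lists with correlated members may be too extreme. Cells of neighbouring structures may have been caught in that pool, which these values cannot decide. Array 2 also had the highest 3' to 5' ratio for 3 of 3 control transcripts, so shortened or poorly amplified RNA may contribute as well. With anlage array 1, 2 or 3 as the single array, 1238, 1080 and 212 genes reached an unadjusted p under 0.05 against 431 in the real grouping; these splits place the collecting duct array with anlage arrays, so the counts do not say which anlage array stands apart.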
